A study of Haloferax mediterranei with 8 samples.

How the data were processed

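Total RNA of 16 cultures of Haloferax mediterranei was compared on 8 arrays of 2 channels each. Per the labels, the groups were the parental strain and the glnA deletion mutant, each in complex medium with 40 mM glutamine (25% salts, 0.5% yeast extract, pH 7.3) and after 72 h without nitrogen, with 4 biological replicates per group in a loop. Replicates 1 and 2 of every group carried Cy5 and replicates 3 and 4 Cy3, so that replicate number and dye go together while each direct comparison had both orientations. All 8 arrays came from 1 slide with 1 scan, so slide or scan could not be a batch.

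The authors deposited 1 scanner file per array, made with Agilent Feature Extraction 10.7.3.1 and a 2-colour protocol per the submitters' processing notes and the file headers. The deposited intensity values are the median brightness of each spot and of its local background, in green and red. The files also give the scanner software's log10 ratio of red over green, background-subtracted and dye-normalized per the file headers, and flags of 0 or 1 per spot. The authors deposited a series table of log2 values, 1 per spot and array, whose scale and direction were found by setting it against the scanner files. It is a ratio of Cy5 over Cy3, with correlations of 0.949 to 0.989 with the scanner's log ratio and array medians from -0.0141 to 0.0568. How its background and dyes were treated is not given in the sources used here.

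The values were processed with limma 3.58.1 in R 4.3.3. Signals were corrected with normexp (offset 50) against the local background and normalized within each array by loess, with control spots at weight 0. The test was planned on mean spot signals. The files hold median signals, which were used in their place. Spots with an outlier flag were left out (221 ORF spots over the 8 arrays), no spot was saturated, and spots of 1 probe were averaged. A probe was kept if it was well above background in all 4 samples of at least 1 group, which kept 11701 of 11703 ORF probes and all 3901 ORFs. The 3 probes of an ORF were averaged, and they had the same sign of change for every ORF named in a comparison. A further 50 probes, named hfx_c and spotted 10 times each, are tied to no ORF and were left out of the ORF tests.

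A linear model of the loop was fitted to the 8 log ratios of each ORF, with the 4 groups and a dye effect, and moderated by eBayes (4 residual and 4.22 prior degrees of freedom). Tests were 2-sided with Benjamini-Hochberg adjustment over the 3901 ORFs and a threshold of 0.05. All 5 comparisons, the alternatives and the rule for named genes were set before the data were examined, except where stated. The precision is limited by the number of arrays. On simulated data with 200 changed ORFs and the fitted spread, the model recovered 75.9% of 2-fold and 99.4% of 4-fold changes for mutant against parent in complex medium, with 5.4% false calls. For the interaction it recovered 54.6% and 98.5%, with 5.2% false calls. The simulated ORFs were independent, no sample was set apart from its group, and fewer ORFs changed than the 718 to 2613 called in the data. The rates therefore describe the model under these settings and need not hold for the data.

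The planned gene lists (nitrogen assimilation, denitrification and other pathways), the replicons and the neighbourhood of glnA needed gene names or locus tags. All array identifiers but bgah name a contig and an ORF, and none of them could be matched to the reference gene table of assembly ASM540632v1, which gives symbols for locus tags and accessions. The lists were therefore not tested, glnA was not reported by name, and no contig was assigned to a replicon. Of the planned rule for named genes, the part that could be applied took, in each comparison, the ORFs with the highest and lowest log2 change among those past the threshold whose 2 direct arrays both went in that direction. At most 2 that rose and 2 that fell are given, and no annotated product could be required. Values of these ORFs in other comparisons, and of ctg2_01606 in complex medium, are given as follow-up.

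In place of the lists, 2 groupings were chosen after the data were seen. ORFs were grouped by contig (contig 2 with 3071 ORFs, contig 3 with 439, contig 4 with 267 and contig 5 with 120, leaving out contig 1 with 3 and 1 identifier without a contig) and tested with camera at an inter-gene correlation of 0.01, adjusted over contigs and comparisons, and again with an estimated correlation. In 200 random sets of these sizes drawn on simulated unchanged data 0% had p under 0.05, and all of 50 sets of 267 ORFs shifted by 0.5 did. The simulated ORFs were independent of each other, so these sets do not test camera on correlated ORFs. In the data the estimated correlation was 0.054 for contig 4 and 0.042 for contig 5. The second grouping was runs of at least 3 ORFs with consecutive numbers on 1 contig, the same strand suffix and calls in the same direction. The text gives a selection of the runs with the largest mean change or the greatest length per direction, not all of them. It also gives selected runs that hold a named ORF or were picked in another comparison.

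Sample levels are normalized log2 signals per channel after loess and Aquantile scaling between arrays. Where all probes of an ORF were below the scanner's criterion for well above background in every sample of a group, the fold is a lower bound on the channel scale. The bound sets the bright group's mean against the dim group's mean of, per sample, the higher of the lowest signal among probes well above background and the ORF's own. Fitted folds are on another scale, and the bound can exceed them. Alternatives covered background correction, normalization, filters, the choice of probe, the dye term, a replicate block, direct arrays only, a separate-channel model, moderation, the threshold, the authors' series table and leaving out each array. Those added after the data were seen are background from negative-control spots and leaving out both arrays of starved parent replicates 1 and 2, or of 3 and 4.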

Results

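The series measured transcript levels in the haloarchaeon Haloferax mediterranei with 2-colour oligonucleotide arrays. It compared the parental strain HM26 (the parent) with a strain deleted for glnA (the mutant), the gene of glutamine synthetase, the enzyme that makes glutamine from glutamate and ammonium. Each strain was sampled in complex medium with 40 mM glutamine, in the middle of exponential growth, and after 72 h in a defined medium without a nitrogen source. The 4 groups held 4 biological replicates each, hybridised as 16 samples on 8 arrays in a loop, so that each of the 4 direct comparisons had 2 arrays with the dyes in opposite orientation. The arrays carried 3 probes for each of 3901 open reading frames (ORFs). The files identify all ORFs but 1 only by a contig and a position on it, and pair these identifiers with no gene name. The deleted gene could therefore not be followed by name, and named pathways could not be examined. ORFs are reported by identifier, by contig and as runs of adjacent ORFs that changed together.

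All 4 starved parent samples stood apart in signal quality. Their median negative-control signal was 588 ± 598 intensity units (SD, n = 4), against 68.8 ± 22.4 in the starved mutant (SD, n = 4), 63.8 ± 14.3 in the parent in complex medium (SD, n = 4) and 59.0 ± 15.1 in the mutant in complex medium (SD, n = 4). The share of spots well above background was 72.0% in the starved parent and averaged 98.4% over the other 12 samples (exact permutation test over 1820 splits, 2-sided, p = 0.000549). This p is the smallest these splits can give. Only the starved parent was set against the others, and the p does not allow for the choice of that group. Of the 3901 ORFs, 2204 were well above background in all 4 starved parent samples and 266 in none of them. All 3901 were in the starved mutant, 3783 in the parent and 3851 in the mutant in complex medium. The median spot signal was higher after starvation in both strains, at 3180 ± 1203 units in the parent and 2366 ± 690 in the mutant (SD, n = 4 each), against 563 ± 192 and 612 ± 124 in complex medium (SD, n = 4 each). Each array was scaled to its own average, so changes in total RNA per cell were outside the measurement and all values are relative.

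**Figure D1:**
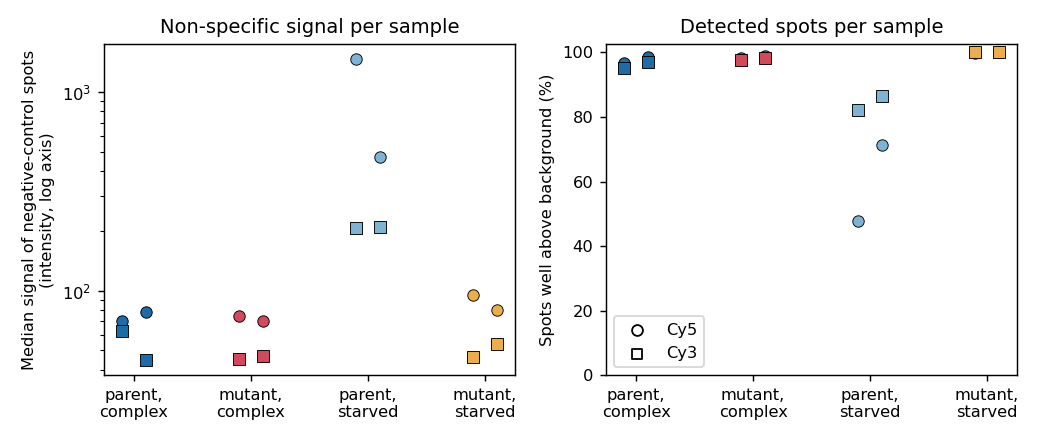
Median signal of the negative-control spots (intensity, log axis, left) and share of spots well above background (percent, right) for the 16 samples, by group, with circles for Cy5 and squares for Cy3. The 4 starved parent samples have negative-control signals of 206 to 1465 and shares of 47.7% to 86.6%, apart from the other 12 samples.

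The first comparison asked how loss of glnA alters transcript levels while glutamine is supplied. In complex medium a small set of ORFs fell far in the mutant. The lowest was ctg2_01172c, with a log2 change of -5.57 (SE 0.42, adjusted p = 0.000259), followed by ctg2_01349c at -5.02 (SE 0.38, adjusted p = 0.000259). The highest were 2 ORFs of 1 run, ctg2_02347 with a log2 change of 4.09 (SE 0.74, adjusted p = 0.0121) and ctg2_02345 with 3.99 (SE 0.70, adjusted p = 0.0109). That run held 5 adjacent ORFs of contig 2 with a mean log2 change of 3.11 ± 1.01 (SD over the ORFs). For both named ORFs of the run the sample levels of the strains overlapped. The normalized log2 signal of ctg2_02347 was 9.44 to 13.97 in the parent and 12.2 to 16.7 in the mutant. For ctg2_02345 it was 8.96 to 12.95 and 11.3 to 16.1. The mean levels differed by 3.29 and 3.41, less than the fitted changes. A run of 8 adjacent ORFs elsewhere on contig 2 was higher by 1.40 ± 0.31, and 4 ORFs of contig 3 were higher by 1.82 ± 0.78. Among the ORFs that fell, ctg2_01349c lay in a run of 3 with a mean of -3.36 ± 1.44, a run of 4 on contig 3 had a mean of -2.54 ± 0.98, and a run of 6 on contig 2 had a mean of -1.91 ± 0.52.

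In all, 718 of 3901 ORFs changed between mutant and parent in complex medium (limma, Benjamini-Hochberg adjusted p under 0.05), 282 higher and 436 lower in the mutant. Changes of at least 4-fold were found in 9 ORFs that rose and 85 that fell. On contig 2, 580 of 3071 ORFs changed, on contig 3 86 of 439, on contig 4 39 of 267 and on contig 5 13 of 120. No contig shifted as a whole against the other ORFs, with adjusted p from 0.256 to 0.922 (camera). The count depended on single arrays: it was 48 without the array that paired parent replicate 1 with mutant replicate 3, and 450 without the array that paired mutant replicate 2 with parent replicate 4. It was 476 without the array of starved parent replicate 1 and complex-medium parent replicate 3, and 420 without that of starved parent replicate 2 and starved mutant replicate 4. Without the first of these 4 arrays ctg2_02347 and ctg2_02345 no longer passed the test (log2 changes of 3.285 and 3.22, adjusted p = 0.142 and 0.134), nor did they with both arrays of starved parent replicates 1 and 2 left out (adjusted p = 0.0792 and 0.0707). With median centring in place of loess, 54.4% of the called ORFs were higher in the mutant, against 39.3%. The share was 6.25% without the first of these 4 arrays and 11.6% with both arrays of starved parent replicates 1 and 2 left out.

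The second comparison asked how the strains differ when no nitrogen source is present. After starvation the ORFs furthest from 0 in the fit were losses in the mutant. Gains are measured against starved parent levels, where 266 ORFs were well above background in no sample, so gains in such ORFs are not measured in full and the 2 directions are not ranked on equal terms. The lowest ORF was ctg2_01606, with a log2 change of -7.92 (SE 0.47, adjusted p = 0.000106). Its normalized log2 signal was 16.2 ± 0.29 in the starved parent and 7.52 ± 1.82 in the starved mutant (SD, n = 4 each), where replicate 1 gave 10.2 and the other 3 samples gave 6.45 to 6.88. In complex medium it was 11.4 ± 0.74 in the parent and 7.12 ± 0.30 in the mutant (SD, n = 4 each), a log2 change of -3.52 (SE 0.47, adjusted p = 0.00478), and -2.93 without the array of mutant replicate 2 and parent replicate 4 (adjusted p = 0.0205). The log2 changes are fitted to the log ratios of the arrays, and the differences of these mean levels are not the same quantity: they are -8.67 under starvation and -4.27 in complex medium. The second lowest, ctg2_00129, had a log2 change of -7.29 (SE 0.72, adjusted p = 0.000333). Its direct arrays gave -4.64 and -9.61, and starved mutant replicate 4 had a normalized log2 signal of 7.14, against 11.8 to 12.97 in the other 3. The size of both losses depended on single arrays. Without the array of starved mutant replicate 1 and starved parent replicate 3 the log2 change was -8.96 for ctg2_01606 and -8.53 for ctg2_00129, and without that of starved parent replicate 2 and starved mutant replicate 4 it was -7.255 and -6.31. With both arrays of starved parent replicates 1 and 2 left out it was -6.67 and -4.98, and with both arrays of replicates 3 and 4 left out -9.34 and -9.71. Immediately before ctg2_00129, a run of 10 adjacent ORFs of contig 2 was lower in the mutant by a mean log2 change of -4.98 ± 0.80 (SD over the ORFs), and a separate run of 4 ORFs on that contig had a mean of -5.01 ± 0.80. The ORFs with the highest log2 changes were ctg3_00125, at 3.51 (SE 0.25, adjusted p = 0.000122), and ctg3_00127, at 3.35 (SE 0.24, adjusted p = 0.000122). Of the 4 starved parent samples, 2 had ctg3_00125 well above background. ctg3_00127 was not well above background in any starved parent sample. By the rule for bounds its level in the mutant was 10.9-fold higher on the channel scale. The fitted fold was 10.2, so the 10.9 is no lower limit to the fitted change. Both lay in a run of 5 adjacent ORFs of contig 3 with a mean of 2.81 ± 0.81, and 9 other adjacent ORFs of contig 3 were higher by 1.42 ± 0.50. These means are fitted values, not bounds: 3 of the 5 and 4 of the 9 ORFs were well above background in no starved parent sample. With those set by the rule for bounds on the channel scale the means were 2.86 and 1.36. The first lies above the fitted mean, so it is no lower limit to it.

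**Figure D2:**
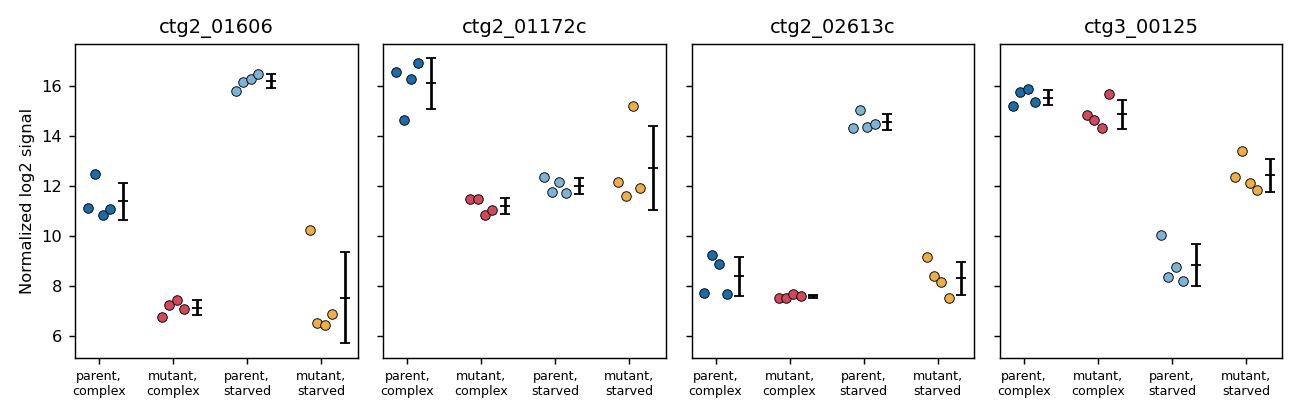
Normalized log2 signal of 4 ORFs in each of the 16 samples, by group, with 4 replicates per group as points and their mean and SD beside them. ctg2_01606 lies between 6.45 and 10.2 in the 8 mutant samples and between 10.9 and 16.5 in the 8 parent samples.

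Under starvation 1449 of 3901 ORFs differed between the strains (limma, adjusted p under 0.05), 699 higher and 750 lower in the mutant. Of these, 22 were at least 4-fold higher and 126 at least 4-fold lower. Contigs 4 and 5 were lower in the mutant as groups. On contig 5, 35 of its 120 ORFs were lower and 5 higher, with a median log2 change of -0.29 (camera adjusted p = 0.00338). On contig 4, 91 of 267 were lower and 38 higher, with a median of -0.27 (camera adjusted p = 0.0161). With an estimated correlation between ORFs the adjusted p was 0.628 for both contigs. With both arrays of starved parent replicates 1 and 2 left out it was 0.0864 for contig 5 and 0.212 for contig 4, and for contig 4 it was 0.0566 without the array of starved parent replicate 2. Of contig 2, 559 ORFs were higher and 540 lower, and of contig 3, 97 higher and 83 lower. The 4 starved parent samples of this comparison are those with bright negative controls. The count was 441 without the array that paired starved parent replicate 2 with starved mutant replicate 4. Leaving out both arrays of starved parent replicates 1 and 2 gave 77, and leaving out both arrays of replicates 3 and 4 gave 573. Among the 2191 ORFs with a probe well above background in all 16 samples, 948 were called. The share of called ORFs that were higher in the mutant also depended on the setting. It was 48.2%, against 59.8% with the scanner software's log ratios, on a scale whose median over all ORFs was shifted by 0.17 in log2. It was 39.0% among those 2191 ORFs, which is in part built in, since that filter removes ORFs that are low in the starved parent: of the called ORFs it removed, 307 were higher and 197 lower in the mutant. It was 22.1% with both arrays of starved parent replicates 1 and 2 left out and 39.8% with both arrays of replicates 3 and 4 left out.

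The third comparison described the response of the parent to 72 h without nitrogen. The starved and complex-medium groups also differ in medium, glutamine supply, growth phase and time. These go together with nitrogen in the design and cannot be told apart from it. Starvation response is used here as a name for the whole shift, in both strains. The ORFs with the highest log2 changes were the neighbours ctg2_02146, at 6.64 (SE 0.57, adjusted p = 3.35e-05), and ctg2_02147, at 6.39 (SE 0.48, adjusted p = 1.89e-05). For ctg2_02146 the log2 change was 5.54 with both arrays of starved parent replicates 1 and 2 left out and 8.0 with both arrays of replicates 3 and 4 left out. The pair belonged to a run of 5 adjacent ORFs that rose by a mean log2 change of 6.02 ± 0.47 (SD over the ORFs). Another run of 4 on contig 2 rose by 5.91 ± 0.35, and the longest run that rose, 16 ORFs of contig 2, by 2.94 ± 1.46. The lowest were ctg2_02318, which was not well above background in any starved parent sample and fell at least 269-fold (adjusted p = 1.4e-06), and ctg3_00317, with a log2 change of -7.40 (SE 0.21, adjusted p = 5.46e-07), which was well above background in 1 of these 4 samples. A run of 5 ORFs of contig 3, the one that holds ctg3_00125, fell with a mean log2 change of -5.55 ± 1.27, and a run of 4 on contig 2 with a mean of -4.81 ± 1.08. In the first of these runs 3 of the 5 ORFs were well above background in no starved parent sample, so its mean is a fitted value and not a bound. With those 3 set by the rule for bounds on the channel scale it was -5.64, a larger fall than the fitted one, so it is no lower limit.

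In the parent 2466 of 3901 ORFs changed (limma, adjusted p under 0.05), 1215 higher and 1251 lower after starvation, and 628 of them changed at least 4-fold. The share higher was 49.3%, against 61.8% among the 2191 ORFs with a probe well above background in all 16 samples. That rise is in part built in, since the filter removes ORFs that are low in the starved parent: of the called ORFs it removed, 301 had risen and 667 had fallen. With the scanner software's log ratios the share was 41.6%, on a scale whose median over all ORFs was -0.183 in log2, against 0.0141. Contig 4 shifted upward against the other ORFs, with 103 of its 267 ORFs higher, 54 lower and a median log2 change of 0.34 (camera adjusted p = 0.0271). With an estimated correlation the adjusted p was 0.632, and the shift also missed the threshold without the array of starved parent replicate 1 (adjusted p = 0.0845), with median centring (adjusted p = 0.0646), with the scanner log ratios (adjusted p = 0.0824) and with both arrays of starved parent replicates 1 and 2 left out (adjusted p = 0.212). On contig 2, 923 ORFs rose and 1071 fell, on contig 3 148 rose and 104 fell, and on contig 5 41 rose and 22 fell, with camera adjusted p from 0.078 to 0.377. The starved group here is again the one with bright negative controls, and the count was 1361 with both arrays of replicates 1 and 2 of that group left out and 1431 with both arrays of replicates 3 and 4 left out.

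The fourth comparison described the same shift in the mutant. The ORFs with the highest log2 changes were ctg2_02986c, at 6.27 (SE 0.76, adjusted p = 0.000143), and ctg2_02903c, at 6.26 (SE 1.08, adjusted p = 0.00103). In complex medium, mutant replicate 1 lay above its group in both, at 12.4 and 11.6 against 9.96 to 10.2 and 8.81 to 9.07. Without the array of this sample and starved mutant replicate 3 the log2 changes were 7.55 and 7.99. For ctg2_02903c the log2 change was 5.41 without the array of mutant replicate 2 and parent replicate 4 in complex medium, and 5.59 without that of starved mutant replicate 2 and complex-medium mutant replicate 4. The first belonged to a run of 5 adjacent ORFs that rose by a mean of 5.69 ± 0.76 (SD over the ORFs). A run of 4 ORFs that had risen by 5.91 in the parent rose by 5.37 ± 0.66. The ORFs that fell furthest were the same pair as in the parent, ctg2_02318 with a log2 change of -7.36 (SE 0.29, adjusted p = 2.05e-06) and ctg3_00317 with -7.25 (SE 0.21, adjusted p = 4.43e-07). The run of 5 ORFs on contig 2 that was higher in the mutant in complex medium fell here with a mean log2 change of -5.01 ± 1.56. The longest run that fell held 15 ORFs of contig 2, with a mean of -1.88 ± 0.78.

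In the mutant 2613 of 3901 ORFs changed (limma, adjusted p under 0.05), 1314 higher and 1299 lower after starvation, and 725 of them changed at least 4-fold. The share higher was 50.3%, against 58.3% among the 2191 ORFs with a probe well above background in all 16 samples, a filter that removed 390 called ORFs that had risen and 632 that had fallen. On contig 2, 1037 rose and 1050 fell, on contig 3 155 rose and 123 fell, on contig 4 86 rose and 90 fell, and on contig 5 36 rose and 36 fell. No contig shifted as a whole (camera adjusted p from 0.523 to 0.922).

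The last comparison asked whether the starvation response itself differed between the strains. Several runs of adjacent ORFs responded in the parent and changed little in the mutant. A run of 4 ORFs on contig 2 rose by a mean log2 change of 4.93 ± 0.69 in the parent (SD over the ORFs), and in the mutant its mean was 0.37 ± 0.27 with none of the 4 past the test. It holds ctg2_02613c, whose response was lower in the mutant by a log2 difference of -5.45 (SE 0.47, adjusted p = 0.000241), and by -4.84 without the array of starved parent replicate 2 and starved mutant replicate 4. The run of 10 ORFs before ctg2_00129 rose by 4.08 in the parent, had a mean of -0.20 ± 0.565 in the mutant with 1 past the test, and passed the test of the difference in all 10. ctg2_00129 had a log2 difference of -5.94 (SE 0.83, adjusted p = 0.00132). Unlike the run before it, it fell in the mutant, with a log2 change of -3.36 (limma adjusted p = 0.00329), and rose by 2.58 in the parent (limma adjusted p = 0.0135). Each of these 2 changes missed the threshold in 1 of the fits without 1 array. The parent's mean levels differ by 1.94, or by 0.927 without replicate 3 in complex medium. With 1 array left out in turn the difference between the strains lay between -6.76 and -5.27. With both arrays of starved parent replicates 1 and 2 left out it was -3.69, and with both arrays of replicates 3 and 4 left out -8.19. In the other direction, the run of 5 ORFs on contig 3 that fell in the parent with a mean of -5.55, a fitted value that includes 3 ORFs well above background in no starved parent sample, had a mean of -1.53 ± 0.90 in the mutant. The highest differences were those of ctg2_02879c, at 6.45 (SE 0.49, adjusted p = 0.00017), and ctg2_01172c, at 5.61 (SE 0.49, adjusted p = 0.000244). Both fell after starvation in the parent, with log2 changes of -3.58 and -3.44, and rose in the mutant, by 2.87 and 2.17. The second rise rests in part on 1 sample: ctg2_01172c had a normalized log2 signal of 15.2 in starved mutant replicate 3 and 11.89 ± 0.27 in the other 3 (SD, n = 3). Without the array of that sample and complex-medium mutant replicate 1 its rise was 1.385 (adjusted p = 0.018), and without that of starved mutant replicate 2 and complex-medium mutant replicate 4 it was 2.99. For ctg2_02879c the same sample gave 15.3 against 13.12 ± 0.13 (SD, n = 3). Its fall in the parent was -4.22 without the array of parent replicate 2 in complex medium and starved parent replicate 4. Some runs responded mainly in the mutant: 9 adjacent ORFs of contig 3 rose by 2.09 ± 0.76 there, with a mean of 0.11 ± 0.46 in the parent, where 1 rose and 1 fell past the test, and 12 of contig 2 fell with a mean of -2.15 ± 0.62, with -0.43 ± 0.33 in the parent. In the run of 9, 4 ORFs were well above background in no starved parent sample, so its parent mean is a fitted value that includes them.

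**Figure D3:**
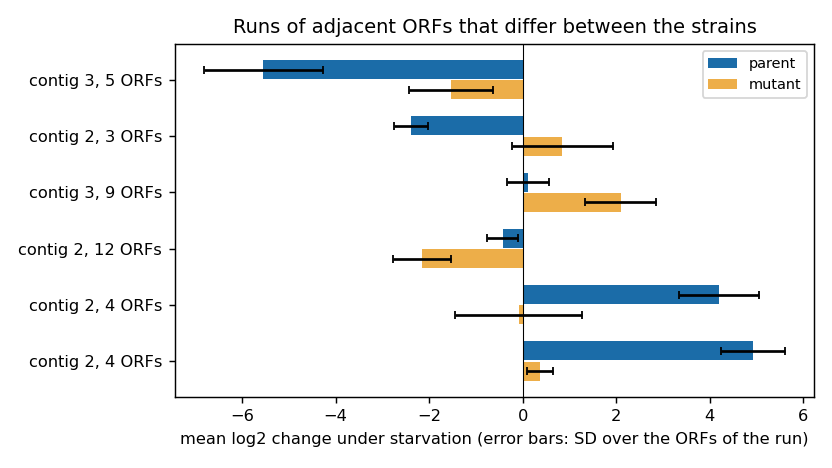
Mean log2 change after starvation, in parent and mutant, of 6 runs of adjacent ORFs with a different response in the strains, with error bars for the SD over the ORFs of a run. The means are fitted values and run from -5.55 to 4.93 in the parent and from -2.15 to 2.09 in the mutant.

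The interaction was significant for 1671 of 3901 ORFs (limma, adjusted p under 0.05), 850 with a higher and 821 with a lower change in the mutant. Of these, 638 changed in the same direction in both strains, with the larger change in the mutant for 412 and in the parent for 226. A further 366 were called only in the parent, 483 only in the mutant, 108 in opposite directions and 76 in neither. The share of called ORFs with a higher change in the mutant was 50.9%. With the scanner software's log ratios it was 56.6%, on a scale whose median over all ORFs was 0.158 in log2, against 0.0226. Among the 2191 ORFs with a probe well above background in all 16 samples it was 43.6%. That filter removed 390 called ORFs with a higher and 280 with a lower change. Contig 5 had a median difference of -0.39, with 40 of 120 ORFs lower and 7 higher (camera adjusted p = 0.00224), and contig 4 a median of -0.32, with 95 of 267 lower and 39 higher (camera adjusted p = 0.00677). With an estimated correlation the adjusted p was 0.628 for both, and for contig 4 it was 0.0932 with both arrays of starved parent replicates 1 and 2 left out. The direct arrays alone gave 968 ORFs. With both arrays of starved parent replicates 1 and 2 left out 297 ORFs were called, and with both arrays of replicates 3 and 4 left out 759.

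Across ORFs, which are not independent replicates, the 2 starvation responses had a Pearson correlation of 0.76. The 4 direct arrays, which share no sample between the strains, gave 0.75. In 100 simulations of the loop without any effect, where shared arrays alone link the estimates, the mean correlation was 0.34. The covariance was 1.94, against 0.0207 simulated. In both strains 874 ORFs rose and 906 fell, where independent lists of the same lengths would share 409 and 417.

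**Figure D4:**
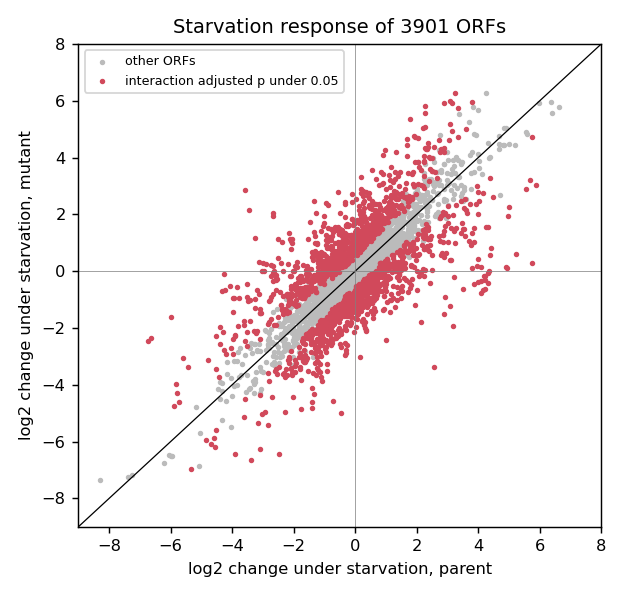
log2 change after starvation in the mutant (vertical axis) against that in the parent (horizontal axis) for each of the 3901 ORFs, with the line of equal change. Red points are the 1671 ORFs whose response differed between the strains and grey points the others.

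Of the ORFs called between the strains in each of the 2 media, 40 were higher and 97 lower in the mutant in both media, where independent lists would share 50.5 and 83.8, and 105 were called in opposite directions. These 2 comparisons share no sample but are linked through the loop fit. Across ORFs the 2 genotype differences had a Pearson correlation of 0.15, against 0.33 in 100 simulations of the loop without any effect, and a covariance of 0.105, against 0.0206 simulated. The direct arrays alone, without that link, gave a correlation of 0.078, with 14 ORFs higher and 53 lower in both media, where independent lists would share 23.7 and 53.4. In opposite directions they gave 72, where independent lists would share 74.4.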

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

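Among the tests in this part, those of the absence of a transcript, of neighbours under starvation alone and of non-specific signal as a part of the calls were chosen after the result was seen, and the others were set before their values were known. Chance splits of the samples were tested for each count of changed ORFs. In each of the 4 pairwise comparisons 34 splits of the 8 samples into 4 and 4 could be fitted, and 1 of the 34, the real one, gave as many ORFs. The real count was 718 for mutant against parent in complex medium, where the highest of the other splits was 114, and 1449 under starvation, where it was 0. For starvation it was 2466 in the parent and 2613 in the mutant, where it was 0 in both. For the interaction 1 of 100 drawn splits, the real one, gave as many as 1671, and the highest other gave 637. The real grouping thus ranked first for all 5 counts. A split that mixes the groups puts any true difference into its spread, so low counts there are in part built in. The pairwise tests also cannot give a share under 1 of 34, so they do not exclude chance.

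The starvation response differed between the strains for 1671 ORFs by the interaction test. The named differences were 6.45 for ctg2_02879c, 5.61 for ctg2_01172c, -5.94 for ctg2_00129 and -5.45 for ctg2_02613c on the log2 scale. As groups, contig 4 had a median difference of -0.32 and contig 5 of -0.39, which did not pass with an estimated correlation (camera adjusted p = 0.628 for both).

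A sample far from the other 3 of its group was found in 12 of 76 groups of values tested, where chance gives about 3.8. The median signal of the parent in complex medium was 849 in replicate 2 against 439 to 501 in the others. The share of spots well above background was 99.9% in starved mutant replicate 1, against 99.98% to 99.99%. Of the ORF levels (normalized log2 signal), starved mutant replicate 3 gave 15.2 for ctg2_01172c and 15.3 for ctg2_02879c, against highest other values of 12.2 and 13.2. Starved parent replicate 4 gave 10.9 for ctg2_01349c against 11.5 to 11.6, replicate 1 gave 9.04 for ctg2_02318 against 7.82 to 7.90, and replicate 3 gave 14.0 for ctg2_02986c against 15.6 to 15.8. Parent replicate 3 in complex medium gave 11.99 for ctg2_00129 against 15.7 to 16.4. Mutant replicate 1 in complex medium was high in 3 ORFs that rise with starvation, at 12.1 for ctg2_02147, 12.4 for ctg2_02986c and 11.6 for ctg2_02903c. Starved mutant replicate 1 gave 10.2 for ctg2_01606 against 6.45 to 6.88.

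Outside the ORF probes, 10 of the 50 probes named hfx_c were well above background in all 16 samples. Fitted on their own, 27 of the 50 changed with starvation in the parent, 20 with starvation in the mutant, 10 between the starved strains and 3 between the strains in complex medium. The interaction was called for 21.

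ctg2_01606 was the one ORF of 3901 with a log2 change under -3 in the mutant in both media, though its change in complex medium was -2.93 without the array of mutant replicate 2 and parent replicate 4. Failed or cross-hybridising probes are argued against, since all 3 probes changed by under -2 in both media. Absence of its transcript from the mutant remains open. The fitted log2 change after starvation was -0.18 in the mutant (SE 0.47, limma adjusted p = 0.756), against a fitted rise of 4.23 in the parent. The ORF was well above background in all 4 starved mutant samples and in 3 in complex medium. All 3901 ORFs were so in the starved mutant, so this criterion cannot decide. The median level of ctg2_01606 over the mutant samples was among the lowest: 0.308% of ORFs had a mean level in the mutant below it. In 18 ORFs every parent sample lay above every mutant sample, with a gap of 0.62 for ctg2_01606 and 0.49 for the next. In 31 ORFs every mutant sample lay above every parent sample. The mean levels differ by 0.40 in the mutant, or by -0.51 without starved mutant replicate 1, and by 4.805 in the parent. As a hypothesis, ctg2_01606 may be the deleted gene, which could be settled by matching its probes to the genome. A change that spreads to its neighbours in both media is argued against: of the 10 ORFs within 5 positions, 0 passed in the same direction in both. A change of its neighbours under starvation alone stays open. There 7 of the 10 passed, against 37.1% of all ORFs, 6 of them lower, and 5.34% of the windows around other ORFs held as many that were lower.

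The starved parent had brighter negative controls, which could in principle create calls between the starved strains. Such signal weighs most on dim spots, but 41.7% of the brightest group of 1300 ORFs were called, against 29.4% of the dimmest 1301. As the whole cause of the calls, non-specific signal is thus argued against only weakly. In starved parent replicate 1 the negative controls had a median of 1464.5 against 4870.5 for all spots, so brighter spots were not free of it. Call rates by brightness were not computed for a comparison without the starved parent. A part of the calls stays open. With both arrays of starved parent replicates 1 and 2 left out, which have the brightest negative controls, 77 ORFs were called (median SE 0.302), against 573 with both arrays of replicates 3 and 4 left out (median SE 0.324), which goes with such a part. The same choices gave 95 and 421 in complex medium, where no starved parent is compared, so the drop does not single out this signal. Also open is a difference in the RNA of the starved parent, which goes with the group in all 4 samples.

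Parent replicate 4 in complex medium differed by over 2 log2 units from the mean of the other 3 in 81 ORFs, against 5 to 32 for the other 3 parent samples. A starved culture in its place is argued against: along the mutant's starvation response, with 0 for the other complex-medium parents and 1 for the starved parents, it lay at 0.171. A partial shift of this culture towards the starved state remains open. The other 3 lay between -0.0689 and -0.0444. Each of them is measured against a mean that includes replicate 4, so their negative values follow in part from its position and add no support. This sample was kept, and the count without its array is given with the comparison in complex medium.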

How the results depend on the processing

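The named ORFs kept their direction and passed the test under all alternatives that could be run, except ctg2_02347 and ctg2_02345 in complex medium without the array of parent replicate 1 and mutant replicate 3, and without both arrays of starved parent replicates 1 and 2. The correlation of the starvation responses lay between 0.74 and 0.78 under the alternatives, and single pairs of direct arrays gave 0.656 and 0.744. Counts are given in the order mutant against parent in complex medium, the same under starvation, starvation in the parent, starvation in the mutant and interaction. Testing only the 2191 ORFs with a probe well above background in all 16 samples gave 386, 948, 1470, 1560 and 971, with fewer ORFs tested. A change of at least 2-fold in addition left 371, 702, 1561, 1760 and 1025, by construction. Leaving out both arrays of starved parent replicates 1 and 2, chosen after the data were seen, gave 95, 77, 1361, 2413 and 297, and both arrays of replicates 3 and 4 gave 421, 573, 1431, 2364 and 759, with fewer arrays in each. The separate-channel model called 1350 ORFs in complex medium and the direct arrays alone 968 for the interaction; the cause was not tested. Leaving out each array in turn gave 48 to 712, 441 to 1414, 1861 to 2463, 2053 to 2604 and 1202 to 1690. All other alternatives stayed within 1.5 times. The shifts of contigs 4 and 5 missed the threshold with an estimated correlation (adjusted p = 0.628 to 0.632), and some missed it in 5 other settings given with the comparisons. Shifts of contigs 2 and 3 that missed the threshold passed it in 9 fits under alternatives. Each had the same direction against the other ORFs as in the main fit. The medians of contig 2 itself lay on both sides of 0 (from -0.081 to 0.083 between the starved strains and from -0.101 to 0.262 with starvation in the parent). The values of -0.081 and 0.262 come from the filter on all 16 samples, where the medians over all ORFs were -0.124 and 0.31. Same-numbered samples did not deviate together (correlations from -0.295 to 0.301, over 0.1 in 7 of 24 pairs, with 6 of 16 samples closest to their own number), and the replicate block gave 719, 1478, 2464, 2620 and 1681. Slide or scan as a block was not run, since there was 1 slide and 1 scan, and contig shifts were not run in the separate-channel model. The ratio of median signal to negative controls was 8.17 in the starved parent, 8.83 in the parent and 10.6 in the mutant in complex medium, and 34.7 in the starved mutant.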

Other observations

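The tests of adjacent ORFs and of a weaker response of the mutant were chosen after the values were seen, and the test for parent RNA in a mutant sample was set before its value was known. ORFs that changed lay together along the contigs. Runs of at least 3 adjacent ORFs called in the same direction held 94 ORFs for mutant against parent in complex medium, 331 under starvation, 700 for starvation in the parent, 785 for starvation in the mutant and 398 for the interaction. Shuffling the calls within contigs 10000 times gave at most 33, 113, 348, 408 and 155 (permutation test, 1-sided p = 1e-04 for each, the smallest these shuffles can give). The lowest ratio of the observed number to the highest of the shuffles was 1.92. Neighbours with the same strand suffix had correlated changes, from 0.423 for mutant against parent in complex medium to 0.644 under starvation, against 0.185 and 0.265 for neighbours with different suffixes. Transcription as operons is a candidate explanation, and it was not tested further because ORF coordinates were not used here.

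The longest such run, 16 ORFs of contig 2, rose with starvation in the parent by a mean log2 change of 2.94. In the mutant its first 9 ORFs rose, by a mean of 3.95, while of the other 7 ORFs 5 passed as lower, and the mean of the 7 was -0.58. A run of 4 ORFs on contig 2 rose by 4.20 in the parent. In the mutant its ORFs went both ways, from -1.94 to 1.35, with 1 past the test as higher and 1 as lower, and all 4 passed the test of the difference. A run of 3 on contig 2 was on average higher in the mutant by 1.30 in complex medium and had a mean log2 change of -1.80 under starvation, with 3 and 2 of its ORFs past the tests. A run of 4 ORFs on contig 4 rose by 3.91 in the mutant and 1.94 in the parent, with 4 and 3 past the tests and all 4 past the test of the difference.

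The ORF with a name in place of a contig identifier, bgah, had a log2 change of 0.15 between the strains in complex medium (limma adjusted p = 0.66). Its normalized log2 signal there was low, at 7.48 ± 0.32 in the parent and 7.53 ± 0.27 in the mutant (SD, n = 4 each). For comparison, ctg2_01606 had 7.12 in the same mutant samples. A difference between the strains may not be measured in full at such levels. bgah was well above background in none of the 4 starved parent samples, so no change against that group is given.

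Starved mutant replicate 1 lay above the other 3 starved mutants at ORFs that are high in the starved parent. A small share of starved parent RNA in this sample may account for it. Over the 17 ORFs at least 5 log2 units lower in the other 3 starved mutants than in the starved parents, replicate 1 was above all 3 in 100%. These ORFs include ctg2_01606, for which this sample is itself flagged. The same test on replicates 2, 3 and 4 gave 0%. Replicate 1 is then among the other 3, so the 0% largely follows from its high values and is no independent control. The implied share of parent signal had quartiles of 2.74% and 3.68%, and for ctg2_01606 it was 1.48%. The excess grew with the parent's level, with a slope of 1.35 (SE 0.18) on the log2 scale, where a constant floor would give none. A constant share of parent signal would give a slope near 1, below the fitted value. Mixed RNA, mixed cultures and spill from the other channel of the same array, which held starved parent replicate 3, were not separated by this test. Such a share would make the estimated losses in the mutant smaller than without it.

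ORFs that rose at least 4-fold on 1 parent array had median log2 changes of 3.102 on the other parent array and 2.33 in the mutant, which could indicate a weaker response of the mutant overall. The reverse choice argues against that: ORFs that rose at least 4-fold on 1 mutant array had medians of 2.81 on the other mutant array and 2.26 in the parent. For ORFs that fell the medians were -2.62 and -1.74. Over all ORFs the SD of the log2 changes was 1.54 in the parent and 1.65 in the mutant.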
